A study of Homo sapiens with 8 samples.

How the data were processed

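KAS-seq maps single-stranded DNA in living cells: N3-kethoxal reacts with unpaired guanines, and the labelled DNA fragments are enriched and sequenced, so that transcription bubbles and other opened DNA appear as peaks. The cells were HEK293T, an established human embryonic kidney line. Per the labels' protocols, cells were kept in medium with or without 0.5 mM vitamin C (ascorbic acid) for 10 min and then labelled with 5 mM N3-kethoxal for 10 min. The series held 8 samples, with 2 labelled and 2 input libraries for each condition. The peak lists of the 4 labelled libraries were used, 2 control and 2 vitamin C libraries, each with its own list, and the 4 input libraries were not analysed here. The cell line field of the labels differed between samples in its number, while every title named HEK293T, and the titles were followed. The labels do not say whether the replicates came from separate cultures, so the exact permutation p-values measure only the spread between these libraries, which may be technical. The p-values for gene lists and for tRNA regions count genes or regions and hold no spread between libraries.

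Per the submitters' processing notes, bcl2fastq 2.19, Trim Galore, cutadapt, Bowtie2 2.4.5, MACS2 2.2.7.1 and deepTools were used, with the genome build hg38. The order and settings of these steps are not given in the sources used here. Each deposited list gives, for every peak, its start, end and summit offset, the authors' fold enrichment (a linear ratio over background), and the authors' −log10 p and −log10 q. The highest q in any list was 0.00999. The authors' fold is each peak's own value and was used to rank or filter peaks within a list and, together with p, to solve for depth as described below. No region was repeated within a list. Peaks on chromosomes 1 to 22 and X were kept. This left out between 4.23% and 5.06% of the peaks of a list.

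Gene positions came from a RefSeq gene table of the assembly GRCh38.p14, the same build as hg38, with 19974 protein-coding genes on these chromosomes. The table used here holds neither strand nor transcripts, so the start of a gene could not be told from its end. The promoter windows planned before the data were examined were therefore placed on both annotated ends of each gene, reaching 1 kb to each side, and are called gene ends. Each peak was assigned by its summit to a gene end, a gene body, a flank (within 5 kb outside a gene) or other sequence, in that order. A gene had a gene-end peak where any base of a peak lay in its window. Such a gene was called lost with a peak in both controls and neither vitamin C library, gained in the opposite case, and kept with a peak in all 4 libraries. Neighbouring genes can share a window, and a peak there counts for each of them.

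Reproducible regions were merged peaks of a group overlapped by a peak in both of its libraries, and a region was met in another library by an overlap of at least 1 bp. Control strength was the mean over both controls of the percentile of the best peak's fold within its own list. Group values were compared by exact two-sided permutation tests, whose smallest possible p with 2 libraries against 2 is 0.333. Gene lists fixed before the data were examined were compared with all other genes with a gene-end peak in both controls by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, for lists with at least 5 such members. Genes are not independent replicates. A further comparison drew 10000 random lists matched on 10 bins of control strength. Shares carry 95% Clopper-Pearson intervals, which cover counting error only.

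Read numbers per library are not in the peak lists. MACS2 computes its fold and p from the fragment pileup and a local background, so both were solved for from each pair of deposited values, with a tolerance of 0.005 in −log10 p. A solution was found for 100% of peaks in each list. In vitamin C replicate 1 it required the labelled library to be scaled by 0.776. The most frequent background, which is the genome-wide mean pileup, gave 0.817 and 0.849 labelled fragments per position in the controls and 1.22 and 0.871 in the vitamin C libraries. The same steps gave input libraries of 1.28, 1.57, 0.776 and 1.44 times the labelled depth.

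Named protein-coding genes followed a rule fixed before the data were examined: the 10 strongest lost, gained and kept genes, and for each list up to 2 lost and up to 2 kept members of the highest control strength. Some genes that this rule selects are not reported here. Alternatives were stricter q and fold thresholds, lists of equal length, all sequences, other windows and overlaps, summit positions, a replicate block and leaving out each library. A common p threshold, loss at the whole region and overlapping peaks in both libraries of a group were added after seeing the data. The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The presence calls and list tests were tested on simulated lists in which 200 genes were lost, 50 gained and 1000 kept among 19974 genes, and 200, 50 and 1000 were called so, with no other gene called. The simulated genes were long, had starts clear of other gene ends, and held a peak in every library of their group. Shared windows and missed calls were not simulated, so this checks the calculation and not the error rate in real lists. The recovery of pileups was tested on simulated peaks and returned 100% of them. These peaks were simulated with the formulas that were solved, so the formulas themselves were not tested.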

Results

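Single-stranded DNA was mapped by KAS-seq in HEK293T cells without treatment and after 10 min in 0.5 mM vitamin C, with 2 labelled libraries per condition. The comparison asks how a short exposure to vitamin C changes the distribution of opened DNA over the genome. The controls held 30351 and 24111 peaks on chromosomes 1 to 22 and X, and the vitamin C libraries held 9816 and 9896. The labelled depth solved from the peak statistics was 0.817 and 0.849 fragments per position in the controls and 1.22 and 0.871 with vitamin C.

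Far fewer regions were called after vitamin C. The mean peak number was 27231 ± 4412 (SD, n = 2) in the controls and 9856 ± 56.6 (SD, n = 2) with vitamin C, a log2 ratio of -1.47. Peaks covered 14.3 ± 1.91 Mb in the controls and 4.82 ± 0.134 Mb with vitamin C, a log2 ratio of -1.57. Both differences exceeded the spread between replicates, and the exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 allow. The median peak was 370 ± 12.7 bp wide in the controls and 354 ± 4.24 bp with vitamin C, with the same exact p of 0.333. In lists of equal length the log2 ratio of covered length was -0.66 and the difference in median width -184 bp instead of -16 bp; the latter was -29.5 bp at −log10 q of at least 5 and between -25 and -7 bp when each library was left out in turn. At gene ends the number of peaks went from a mean of 6128.5 to 2758.5, and in gene bodies from 15285.5 to 4728.

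**Figure D1:**
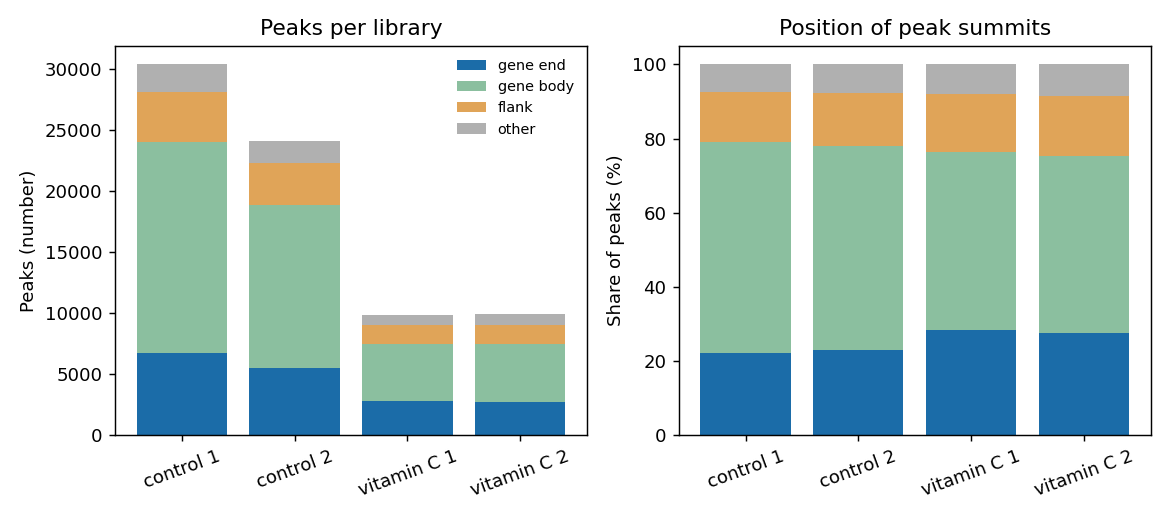
Stacked bars give, for each of the 4 libraries, the number of peaks (left) and the share of peaks in percent (right) whose summits lay at gene ends, in gene bodies, in flanks within 5 kb of genes or elsewhere. The 2 vitamin C libraries held 9816 and 9896 peaks against 30351 and 24111 in the controls.

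Gene bodies made up a smaller part of the vitamin C lists and gene ends a larger part. Summits in gene bodies were 56.9% (95% interval 56.3 to 57.4) and 55.2% (54.6 to 55.8) of the control peaks and 48.1% (47.1 to 49.1) and 47.8% (46.8 to 48.8) of the vitamin C peaks. Gene ends held 22.2% and 22.9% of control peaks and 28.4% and 27.6% of vitamin C peaks. The flanks held 13.9 ± 0.541% in the controls and 15.8 ± 0.333% with vitamin C (SD, n = 2), and other sequence 7.52 ± 0.109% and 8.23 ± 0.455%. The exact two-sided permutation p was 0.333 for each class. The shift depended on the length of the lists: among the 9816 peaks of lowest q in each list, the gene-end share differed by -0.87 percentage points (vitamin C minus control), the gene-body share by 0.30, the flank share by 0.57 and the share of other sequence by 0. The difference of 0.710 points in other sequence was 0.389 to 1.03 when each library was left out in turn, 1.10 at −log10 q of at least 5 and 1.24 with all sequences.

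The vitamin C regions lay almost wholly within the control regions. Of 5834 regions found in both vitamin C libraries, 94.4% (95% interval 93.8 to 95.0) were met by a peak in both controls and 48 in neither. Of 15177 regions found in both controls, 33.1% (32.4 to 33.9) were met in both vitamin C libraries, 24.9% in 1 and 42.0% in neither. The Jaccard index of covered bases was 0.416 between the controls, 0.439 between the vitamin C libraries and 0.254 to 0.311 between conditions. The shorter vitamin C lists limit the index between conditions even where their peaks lie within control peaks. These values therefore do not show a difference in position. In lists of equal length the 2 directions came closer, with 65.4% of control regions met with vitamin C and 73.8% of vitamin C regions met in the controls. The control regions met were 16.0% where 50% of the region had to be covered and 17.7% without control replicate 2.

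Retention was higher at stronger control peaks, except among the weakest. Control regions were divided by strength into 10 bins of equal size. In the weakest bin 13.6% (95% interval 11.9 to 15.5) were met in both vitamin C libraries, in the second 10.2% (8.73 to 11.8), in the bin next to the strongest 64.3% (61.8 to 66.7) and in the strongest 94.9% (93.6 to 95.9). Of the strongest 1517 regions, 11 were met in neither. Regions with summits in gene bodies were kept in 27.5% of cases and those at gene ends in 39.4%. Regions of the other classes in the same bins gave 27.6% for the gene bodies and 40.1% for the gene ends. These are averages over bins that differed in both directions. In the weakest bin 15.3% of gene bodies (13.1 to 17.7) and 6.67% of gene ends (3.78 to 10.8) were kept. In the strongest, 91.5% of gene bodies (88.2 to 94.1) and 98.0% of flanks (95.4 to 99.3) were kept.

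**Figure D2:**
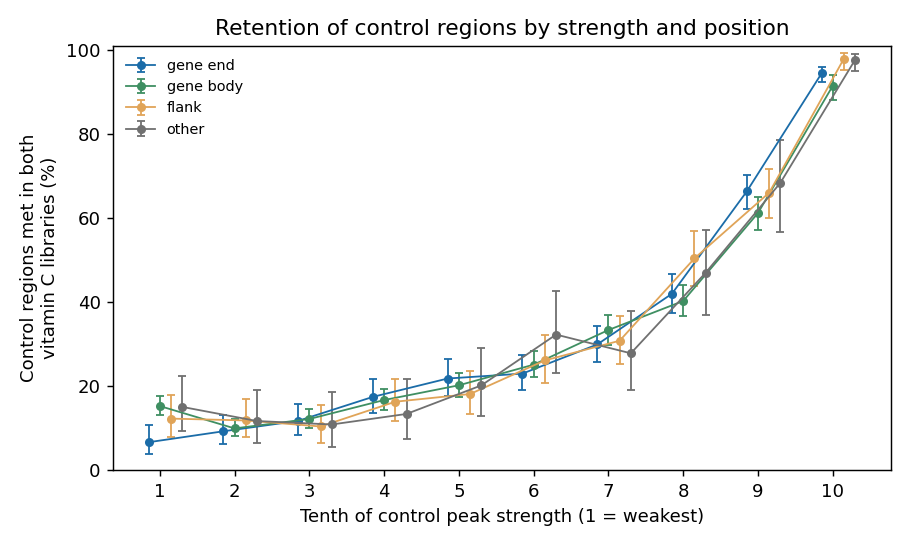
The vertical axis gives the percent of reproducible control regions met in both vitamin C libraries, and the horizontal axis the bin of control peak strength, from weakest (1) to strongest (10). Points are gene ends, gene bodies, flanks and other sequence, and bars are 95% Clopper-Pearson intervals; in the strongest bin gene ends were kept in 94.4% of cases and gene bodies in 91.5%.

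Among protein-coding genes, 4638 had a gene-end peak in both controls. Of these, 1385 had none in either vitamin C library (29.9%, 95% interval 28.5 to 31.2), 1065 had one in 1 of them and 2188 had one in both (47.2%, 45.7 to 48.6). The opposite pattern, a peak in both vitamin C libraries and neither control, was seen at 4 genes. The peaks of a gene in the 2 controls need not be the same peak: 1171 of the lost genes and 2085 of the kept ones had overlapping peaks in both libraries of each group in which they had peaks, a count chosen after seeing the data. In lists of equal length there were 233 lost and 99 gained genes. Lost genes numbered 2618 without control replicate 2, and gained genes 57 and 19 without control replicates 1 and 2, and 42 and 34 without vitamin C replicates 1 and 2. With summits in the window there were 30 gained genes, and 7 at −log10 q of at least 5. In 5 groups of genes by control strength, 11.9% of the weakest group and 94.0% of the strongest were kept, a difference of 82.1 points that was 44.2 points in lists of equal length, and 581 of 928 and 9 of 927 were lost.

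Apart from HEXIM1, the strongest control replicate 1 peak at each of the 10 strongest kept gene ends covered annotated small RNA genes. It also did so at the 2 strongest lost ones, FCGR3A and KCTD2. Over all kept genes, the strongest peak in control replicate 1 covered a tRNA, snoRNA or small nuclear RNA gene at 100 of 2188 (4.57%), and over all lost genes at 2 of 1385; these counts were chosen after the data were seen and not tested. HEXIM1 (chromosome 17, 45148475 to 45152099), which encodes an inhibitor of the elongation kinase P-TEFb, had peaks in all 4 libraries at a mean percentile of 99.9. ALOXE3 and HES7 shared a peak that covers 4 annotated tRNA genes, and the peaks at NCOA7, H4C8, PLXDC1 and AGBL5 also covered tRNA genes. The peak at TAF12 covered the small nuclear RNA gene RNU11. At NOP56 and IDH3B the control replicate 1 peak, which began at 2653453, covered snoRNA genes. The strongest peaks of control replicate 2 and the vitamin C libraries began at 2658522, 2658540 and 2658679, past the end of NOP56 at 2658393. The signal at such shared peaks cannot be assigned to 1 of the genes.

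The strongest lost genes by the fixed rule were FCGR3A, KCTD2, TRIM65, FCGR3B, NFE2, ZNF649, DDTL, NDUFA11, CDIPT and MPHOSPH8. At 8 of these 10, a vitamin C peak still met the control peak that reached the window, but ended outside the window. Only NDUFA11, a subunit of respiratory complex I (chromosome 19, 5891229 to 5903790), and MPHOSPH8, a chromodomain protein (chromosome 13, 19633659 to 19673441), also lost the region itself. Over all lost genes the region was lost at 1266 (91.4%). Chosen after their values were seen, the next genes lost at the region were HSPB9 and KAT2A, which share a peak, then ATP6V1A, KATNAL2, EIF4E, UBR4, PRMT6 and PLCXD2. KAT2A is a histone acetyltransferase, PRMT6 an arginine methyltransferase and EIF4E the cap-binding protein of translation initiation. The gained genes were VASH1 (chromosome 14), MTO1 (chromosome 6), GPCPD1 (chromosome 20) and EMD (chromosome X), at mean vitamin C percentiles of 65.6, 46.7, 36.1 and 24.0. Only VASH1 was gained under each alternative: GPCPD1 and EMD were not at −log10 q of at least 5 or at the fold threshold, MTO1 and EMD were not with a window of 2 kb, and GPCPD1 was not with a window of 500 bp.

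Cytosolic ribosomal protein genes kept nearly all their gene-end peaks. Of 80 with a peak in both controls, 75 were kept and 3 lost (3.75%, 95% interval 0.780 to 10.6), against 30.3% of other genes (Fisher's exact test, adjusted p = 7.1e-08). RPL3 and RPL18 were the strongest kept members, and RPL26L1 was among the lost. Of 44 replication-dependent histone genes 1, H3C12, was lost (2.27%, adjusted p = 6.1e-05 by Fisher's exact test), and H4C8 and H2AC19 were the strongest of the 37 kept. None of 27 splicing factor genes was lost (adjusted p = 0.00094 by Fisher's exact test), and 25 were kept, led by SRSF3 and DDX5. These 3 of the 19 lists tested passed the threshold, all with less loss than other genes. In lists of equal length 0 lists passed, while 6 did so without control replicate 1, 5 without either vitamin C replicate and 5 when genes not kept in both were counted instead of lost ones. The control peaks of the 3 lists were strong, at median percentiles between 96.5 and 97.6. In a permutation test against random lists matched on control strength no list passed (lowest raw p = 0.0566, for glycolysis, adjusted p = 1), and the raw p was 0.956 for ribosomal protein, 0.146 for histone and 0.629 for splicing factor genes.

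**Figure D3:**
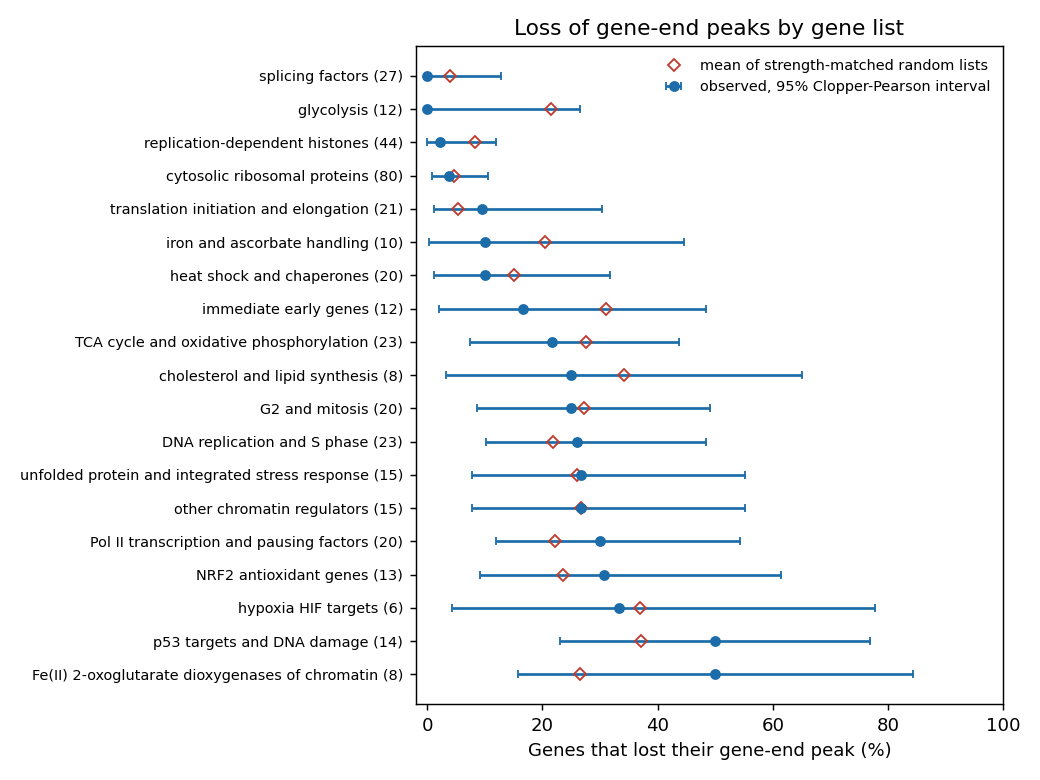
For each of 19 gene lists, the horizontal axis gives the percent of genes with a gene-end peak in both controls (number in brackets) that had none in either vitamin C library. Filled points with bars are observed values with 95% Clopper-Pearson intervals, and open diamonds are means of random lists matched on control strength; ribosomal protein genes lost 3.75% against 4.59% in matched lists, and histone genes 2.27% against 8.29%.

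The lists chosen for the chemistry of vitamin C did not pass the test. Of 8 genes for Fe(II)- and 2-oxoglutarate-dependent dioxygenases of chromatin with a peak in both controls, 4 were lost, among them RIOX2 and ALKBH1, and 1, the histone demethylase KDM4A, was kept (50% lost, 95% interval 15.7 to 84.3). Of 10 iron and ascorbate handling genes 1, NCOA4, was lost, and CYB5R3 and PCBP2 were the strongest kept. NRF2 antioxidant genes lost 4 of 13, with MAFG and SQSTM1 lost and PRDX1 and TXN kept. Hypoxia-responsive genes lost 2 of 6, MXI1 and NDRG1, while VEGFA and DDIT4 were kept. Their adjusted p-values by Fisher's exact test were 0.59, 0.63, 1 and 1.

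Energy metabolism and stress lists also stayed short of the threshold. None of 12 glycolysis genes was lost (adjusted p = 0.11 by Fisher's exact test), with GAPDH and PKM the strongest kept. Among 23 genes of the TCA cycle and oxidative phosphorylation 5 were lost, including SUCLG1 and NDUFA1, and IDH3B and ATP5F1B were kept. Heat shock and chaperone genes lost 2 of 20, DNAJB1 and HSPA1B, and kept HSP90AB1 and HSPA8. Immediate early genes lost 2 of 12, NFKBIA and KLF10, and kept JUN and KLF6. Among genes of the unfolded protein and integrated stress responses 4 of 15 were lost, including PPP1R15A and ATF6, with ATF4 and PHGDH kept. The p53 and DNA damage list lost 7 of 14, including PPM1D and TP53I3, and kept GADD45B and POLH (adjusted p = 0.38 by Fisher's exact test). Cholesterol and lipid synthesis genes lost 2 of 8, and FDPS was among those kept.

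Among regulators of transcription, 6 of 20 genes for Pol II transcription and pausing factors were lost, including CDK9, the kinase of P-TEFb, and MED1, while HEXIM1 and GTF2A1 were kept. Other chromatin regulators lost 4 of 15, including EP300 and RAD21, and kept BRD2 and EED. Translation factors lost 2 of 21, EIF4E and EIF3B, and kept TPT1 and EIF4A1. DNA replication genes lost 6 of 23, including GINS1 and CCNE1, and kept CDC6 and E2F1. Genes of G2 and mitosis lost 5 of 20, including HMMR and PLK1, and kept BIRC5 and CDK1. None of these lists passed (lowest adjusted p = 0.17 by Fisher's exact test, translation). At H3C12, NFKBIA, PPP1R15A, GINS1, CCNE1 and HMMR, all named above as lost, a vitamin C peak outside the window still met a control peak that reached the window. At NFKBIA, PPP1R15A and HMMR this was not the strongest control peak, which no vitamin C peak met in either control. At H3C12 and HSPA1B no peak of one control at the gene overlapped a peak of the other, and at DNAJB1, NDUFA1, MXI1, NDRG1 and PPP1R15A the strongest peaks of the controls were different ones. Among the named kept genes, the strongest control peaks did not overlap at VEGFA, HSPA8, ATP5F1B, DDX5, EED and FDPS. The strongest vitamin C peaks did not overlap at VEGFA, HSPA8, PHGDH, PRDX1 and PCBP2.

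Genes expected to be silent had almost no peaks. Of 40 genes of other tissues, 1 had a gene-end peak in control replicate 1 and none in the other libraries. Of 390 olfactory receptor genes, 1 had a peak in each library, OR1F1, whose peak covers a tRNA gene. Of 37 non-coding RNA genes fixed beforehand, 34 had a peak in all 4 libraries, among them RN7SK, RMRP, RPPH1, MALAT1 and NEAT1. TUG1 and OIP5-AS1 had peaks in both controls and neither vitamin C library, and RNU2-1 had none in any library.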

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

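Numbers of peaks, covered length, and the excess of lost over gained genes kept their direction under each alternative run, while the position of peaks did not. In lists of equal length, cut to the 9816 peaks of lowest q, the log2 ratio of covered length was -0.66, the width difference -184 bp, and the differences in share -0.87 points for gene ends, 0.30 for gene bodies, 0.57 for flanks and 0 for other sequence. Control regions met with vitamin C were then 65.4%, vitamin C regions met in the controls 73.8%, lost genes 233, gained genes 99, the difference in retention between the strongest and weakest of the 5 groups 44.2 points, lists with a difference 0, and the within minus between Jaccard index 0.061. Of the 1385 lost genes 232 were among these 233. Equal lengths remove the difference in peak number by construction. At −log10 q of at least 5 the width difference was -29.5 bp, the other share 1.10 points, the regions met 34.8% and 93.4%, gained genes 7 and the retention difference 79.0 points. A fold of at least 4.17 gave 32.3% and 91.4% of regions met. All sequences gave 1.24 points for the other share. Requiring 50% of the region gave 16.0% and 91.0%, and widening peaks by 500 bp 36.8% and 95.9%. A window of 500 bp gave 3.80 points for gene ends and a retention difference of 78.1 points, and a window of 2 kb gave 7.55 points. Summits in the window gave 30 gained genes. Counting genes not kept in both as the outcome gave 5 lists, and strength-matched random lists gave 0. Apart from the equal lengths and the matching, the cause was not tested. Leaving out each library in turn gave log2 ratios of -1.62 to -1.29 for peaks and -1.70 to -1.42 for covered length, 17.7% to 46.4% and 79.2% to 97.7% of regions met, 1855 to 2618 lost genes, 19 to 57 gained genes, retention differences of 71.5 to 79.0 points, 4 to 6 lists and Jaccard differences of 0.124 to 0.176; 1 library then stands for its group, which widens these counts by construction, and lost genes rose to 2618 without control replicate 2. Chosen after seeing the data, a common −log10 p of at least 5 gave a log2 ratio of peaks of -1.44 and 1349 lost genes, loss at the region gave 1266, and overlapping peaks in both libraries gave 1171 lost genes and 3 lists. With replicate number as a block the values were -1.46 for peaks, -1.56 for covered length, -16 bp for width and 5.44 points for gene ends, which changed no direction. Over genes, the differences between replicates 1 and 2 had a correlation of -0.02 between the conditions. Whether same-numbered libraries were paired stays open, since the labels do not give the origin of the replicates. Counting each row of the lists changed nothing, as no region was repeated, and windows on every transcript were not run because the gene table used here holds no transcripts. Depth was solved for and not counted, so how many weak regions each library missed is unknown.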

Other observations

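The tests and values in this part were chosen after the data were seen. tRNA genes, transcribed by RNA polymerase III, kept their called peaks to a large extent. The presence of a peak does not measure how much DNA was opened. Of 443 annotated tRNA genes, 312 and 311 had a peak within 250 bp in the controls and 295 and 294 with vitamin C, and of 305 with a peak in both controls 291 were kept in both vitamin C libraries (95.4%, 95% interval 92.4 to 97.5). All 39 small nuclear RNA genes with a peak in both controls were kept. At the same distance 59.4% of snoRNA genes (51.5 to 67.0), 44.5% of protein-coding genes (42.6 to 46.4), 43.8% of lncRNA genes (39.7 to 47.9) and 40.8% of miRNA genes (29.3 to 53.2) were kept.

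The length covered by peaks was also measured within single genes. In 297 genes with a mean of at least 5000 bp covered in the controls, the vitamin C coverage had a median of 33.4% of the control coverage, with quartiles of 24.8% and 47.6%, against 33.8% for the covered length over all chromosomes analysed. Choosing genes by their control coverage favours a fall, and whether they differed from one another was not tested. SLIT2, an axon guidance gene, had the longest coverage, 47978 ± 750 bp in the controls and 15699.5 ± 360 bp with vitamin C (SD, n = 2), or 32.7%. PRRC2B went from 19668.5 ± 2749 bp to 3946.5 ± 2379 bp (SD, n = 2), with 5629 and 2264 bp in the vitamin C libraries. NPM1, encoding nucleophosmin, went from 20544 ± 717 to 12647.5 ± 122 bp (SD, n = 2), or 61.6%, and RCC1 kept 87.4%, the latter with 14401 and 12851 bp in the controls against 11856 and 11961 bp with vitamin C. RCC1 overlaps the non-coding gene SNHG3, which had peaks in all 4 libraries, so this coverage cannot be assigned to RCC1 alone. Covered length depends on how much was called in each list.

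On 2 unplaced or unlocalised sequences that carry ribosomal RNA gene copies, peaks numbered 35 and 35 in the controls and 22 and 35 with vitamin C, and covered 26839, 32168, 21809 and 31627 bp. The percent of control regions kept ranged from 21.8% on chromosome 18 to 41.4% on chromosome 6.

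The first pattern weighed was the lower number of peaks with vitamin C. A shallower labelled library does not account for it, because the lower vitamin C depth was above the higher control depth by 0.0369 on the log2 scale. This rests on the caller's published formula and not on read counts. Higher local input stays open. The median background of the peaks was 1.05 and 1.27 fragments in the controls and 1.44 and 1.39 with vitamin C. Divided by the genome-wide background it was 1.281 and 1.497 in the controls and 1.511 and 1.594 with vitamin C. The higher vitamin C value exceeded the lower control value by 0.32 on the log2 scale, which is the widest pair. The lower vitamin C value lay only slightly above the higher control value. This background is seen only at called peaks, and calling depends on it. Weaker labelling or capture in the vitamin C libraries cannot be told apart from an effect of vitamin C. Gene bodies were kept -0.11 percentage points away from regions of equal strength, but this averages bins that differed in opposite directions. In the weakest bin 15.3% of gene bodies were kept, against 6.67% of gene ends, 12.3% of flanks and 15.1% of other sequence. In the strongest bin these were 91.5%, against 94.4%, 98.0% and 97.7%. The average therefore does not show a uniform loss of signal, and it does not separate the origins.

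The second pattern was the low loss in the ribosomal protein, histone and splicing factor lists. A candidate explanation is the strength of their control peaks: in permutation against lists matched on strength the lowest raw p of the 3 was 0.146. Ribosomal protein genes lost 3 where matched lists lost a mean of 3.68, histone genes 1 where they lost 3.65 and splicing factor genes 0 where they lost 1.05. A p that misses the threshold does not show that these lists behave as other genes of equal strength do.

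The third pattern was the retention of control regions at tRNA genes. Of 250 such regions 236 were kept. Much of this may come from their strong control peaks. The number kept was drawn 10000 times as binomial counts at the kept rate of other regions in the same strength bins. The mean number kept was 217.0 with 10 bins, 226.2 with 20 and 228.4 to 228.6 with 50 to 200. With 10 bins the two-sided p from these draws was 0.00020, the smallest they allow. The highest p over these 5 bin widths was 0.0176, with 50 bins, but tRNA genes lie in clusters, so the regions are not independent and this p is too small. In the strongest of the 50 bins all 168 other regions were kept too, and strength is measured with error, so whether it accounts for the remaining excess stays open.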
